A study of Penicillium oxalicum with 12 samples.

How the data were processed

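RNA sequencing libraries of Penicillium oxalicum, a filamentous fungus that secretes plant cell wall degrading enzymes, were compared. Per the labels, mycelium was grown for 24 h in liquid medium with 2% Avicel, a microcrystalline cellulose, and total RNA was extracted. The 12 libraries fell into 4 groups of 3, named here deletion (the mutant of POX07071), overexpression (the strain labelled OE7071), Ku70 of the deletion set and Ku70 of the overexpression set. Both Ku70 groups carry Ku70 strain names, and the sample titles tie each to its own set. Ku70 is a DNA end-joining protein, and fungal strains lacking it are commonly used as parents for gene targeting. Replicates carry the letters F, S and T. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

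Each library came as a table of 9834 genes with an identifier, an expected count and an FPKM value. Per the file headers, the deposited expected counts are estimated read counts per gene, of the kind RSEM gives, and were not normalized. Per the file headers, the deposited FPKM values are fragments scaled to gene length and to the mapped fragments of the library. The submitters' processing notes name BWA 0.7.10-r789, Bowtie2 2.1.0, RSEM 1.2.12 and DESeq2 without saying what each was used for. The genome build, the annotation and the strand setting are not given in the sources used here, so antisense and overlapping genes could not be told apart from their partners. RSEM divides reads that match several genes, so genes with near-identical copies are uncertain. The ratio of expected count to FPKM within a gene was constant over libraries, with 5200 of 5200 well-expressed genes within 3%.

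Libraries held 13882665 to 15300876 expected counts. A gene at 0 was given a floor of 3 counts per library, and folds against such a group are lower bounds, taken from the highest floor in the group, on the FPKM scale for POX07071 and on TMM-scaled counts for other genes. Floors and counting intervals cover counting error only, since reads are not independent molecules.

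Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling) in R 4.3.3. The design fixed before the data were examined foresaw limma on log2(FPKM + 1), with edgeR in its place if counts were given, which they were. All 12 libraries entered a single fit with a mean per group and 8 residual degrees of freedom. The 8877 genes with a mean FPKM of at least 1 were tested, and 957 genes fell under that limit. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were deletion against its Ku70 group, overexpression against its Ku70 group, the Ku70 groups against each other (overexpression set over deletion set), and the difference of the 2 effects (deletion minus overexpression). POX07071 was also compared by a two-sided exact permutation test. Levels are given as mean FPKM ± SD with n = 3, and log2 fold changes with their SE. Unless a lower bound, a count ratio or another method is named, folds come from the edgeR fit on TMM-scaled counts. They can therefore differ from the ratio of the FPKM means printed beside them. The SE in edgeR was taken as the absolute log2 fold change divided by the square root of the test's F statistic.

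The reference table used for gene names (assembly ASM172317v3 of strain HP7-1, 9964 genes) matched 0 of the 9834 identifiers, so the identifiers are printed as the files give them. For the same reason the 27 gene lists defined by product name had no members, and none was tested. The remaining list held 23 identifiers of cellulase and xylanase genes recalled from published work on strain HP7-1. It was fixed before the data were examined, and neither the files nor the reference table pair its identifiers with products. Enzyme names given for some members come from the same recollection. The list was tested with camera (limma 3.58.1) with an estimated correlation between genes. It was the only list tested, so its p needed no adjustment over lists.

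By the rule for named genes, the text names POX07071, the list members as a group, and the 2 called genes with the largest fitted rise and the 2 with the largest fitted fall in each of the deletion and overexpression comparisons, among genes whose libraries did not overlap and whose mean FPKM was at least 10. Any other gene is said to have been chosen after its values were seen.

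The scripts were tested on simulated counts for 8877 genes, with 50 genes changed at each of 1.5-fold, 2-fold, 4-fold and 8-fold per comparison. Of 50 genes changed 2-fold, 86% were recovered for the deletion comparison, 84% for overexpression, 88% for the Ku70 groups and 56% for the difference of effects. At 1.5-fold these shares were 22%, 34%, 46% and 12%. Far more genes were called in the data, and the adjusted p limit is then less strict. The simulated shares therefore need not hold for the data. Genes simulated as unchanged made up 11.1%, 6.06%, 7.43% and 8.28% of the calls, in the same order. The list test passed 0.05 in 0 of 20 simulations without an effect. Genes were simulated independently, so this does not show how the test behaves for a list whose members are correlated.

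Alternatives were DESeq2 1.42.0, limma on log2 FPKM with pseudocounts of 0.1, 1 and 5 and without a trend, quantile, median ratio and total count scaling, no low-value filter, a mean FPKM of at least 10, only the 2 groups compared, the letters as blocks, an absolute log2 fold change of at least 1, the control of the other set, other list tests (camera with a preset correlation of 0.01, and fry) and each library left out in turn. Quantile scaling was used with limma on log2(FPKM + 1), and median ratio and total count scaling with edgeR. Figures were drawn with matplotlib 3.10.9.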

Results

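Transcript levels of 9834 genes were measured in P. oxalicum mycelium after 24 h on 2% Avicel, in 3 libraries each of a POX07071 deletion strain, a POX07071 overexpression strain and the Ku70 group of either set. The stated purpose was to learn how POX07071, described in the labels as a G protein, affects transcription of cellulase and xylanase genes. Depth ranged from 13882665 to 15300876 expected counts per library, and 294 to 474 genes per library had no count. Replicates correlated at r = 0.9753 to 0.9943 (log2 CPM, across genes, which are not independent replicates). Library T of the Ku70 deletion set stood apart from F and S (r = 0.9753 and 0.9767, against 0.9927 between F and S), and library S of the Ku70 overexpression set from F and T (r = 0.9835 and 0.9839, against 0.9921 between F and T). To a smaller extent, so did library T of the overexpression group from F and S (r = 0.9886 and 0.9888, against 0.9943 between F and S).

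POX07071 had 0 counts in each of the 3 deletion libraries, where the floor of 3 counts corresponded to 0.829 to 0.88 FPKM. Its level in the Ku70 libraries of the deletion set was 201.9 ± 10.08 FPKM (SD, n = 3), so the transcript was at least 229-fold lower in the deletion strain. In the overexpression strain POX07071 reached 6669 ± 485.7 FPKM against 320.3 ± 20.26 FPKM in its Ku70 group (SD, n = 3), 20.9-fold higher (log2 fold change 4.39, SE 0.12, edgeR Benjamini-Hochberg adjusted p = 2.44e-09). The exact permutation p was 0.1 in either comparison, the smallest that 3 against 3 libraries allow. The labels and the POX07071 levels matched in all 12 libraries.

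**Figure D1:**
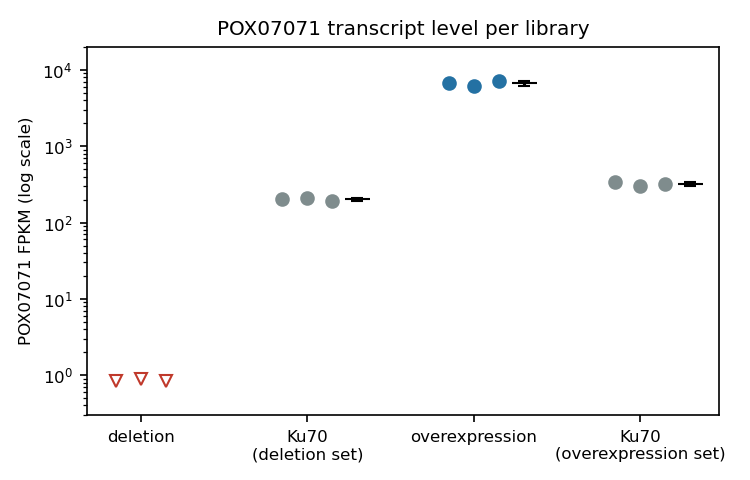
FPKM of POX07071 (log scale) in each of the 12 libraries, grouped by strain and set, with replicates F, S and T from left to right and the group mean ± SD as a black bar. Open triangles mark deletion libraries at 0 counts, drawn at the FPKM of 3 counts; overexpression libraries lie between 6185.33 and 7156.71 FPKM.

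Deletion of POX07071 went with lower transcript levels of most cellulase and xylanase genes of the list. Of the 23 members, 20 fell, 1 rose (POX07963, log2 fold change 0.91, SE 0.16) and 2 were not called (POX02740 and POX08484). The cellobiohydrolase gene POX05587, whose product releases cellobiose from cellulose chain ends, fell from 2310 ± 994 to 620 ± 119 FPKM (4.15-fold lower, SD, n = 3). The endoglucanase gene POX05571 fell from 673 ± 116 to 206 ± 39.5 FPKM (3.61-fold lower). The xylanase genes POX00063 and POX06783 fell 9.31-fold and 8.15-fold, from 1400 ± 230 to 165 ± 29.6 FPKM and from 627 ± 120 to 84.9 ± 16.6 FPKM. Some other abundant members fell less. The cellobiohydrolase gene POX04786 fell 2.29-fold, from 3390 ± 824 to 1640 ± 295 FPKM, and the endoglucanase gene POX01166 fell 2.07-fold. The xylanase gene POX08484, which was not called, was 1.51-fold lower.

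The largest fall on the list was that of POX06601, from 167 ± 49.6 to 3.35 ± 0.95 FPKM (log2 fold change -5.79, SE 0.65, edgeR adjusted p = 1.39e-05). The list median was a log2 fold change of -1.58 (2.98-fold lower). Adjusted over the list alone, 21 members were lower and 1 higher, and 26.1% of all tested genes were lower. Against all other genes the list did not pass (camera with an estimated correlation of 0.381 between members, p = 0.111), whereas camera with a preset correlation of 0.01 gave p = 6.85e-07. Without library T of the Ku70 deletion set, 19 members were lower with a median of -1.355. POX03641 (log2 fold change -0.53, edgeR adjusted p = 0.0649) and POX08990 (-0.72, adjusted p = 0.0524) then lost their calls, and POX08484 (-0.81, adjusted p = 0.0103) gained one. POX03641 also lost its call without library T of the deletion group (-1.25, edgeR adjusted p = 0.0683) and POX08990 without library S (-0.90, adjusted p = 0.0586), while POX08484 was also called without library T of the overexpression group (adjusted p = 0.0267) or S of its Ku70 group (adjusted p = 0.0447).

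Of the genes with the highest fitted rises in the deletion strain, POX03250 rose from 2.59 ± 1.24 to 15500 ± 515 FPKM (log2 fold change 12.39, SE 0.31, edgeR adjusted p = 3.8e-11). POX03798 stood at 572 ± 64.2 FPKM against 1 count in the 3 Ku70 libraries, a ratio of 6110 (95% counting interval 1100 to 241000). POX00555 fell from 77.9 ± 17.2 to 0.817 ± 0.212 FPKM (log2 fold change -6.70, SE 0.44) and POX09166 from 428 ± 124 to 6.31 ± 0.612 FPKM (-6.21, SE 0.25). The size of both falls depended on the control. POX00555 had 16 to 29 counts in the deletion libraries, 1772 to 2659 in their Ku70 group and 34 to 129 in the other Ku70 group. For POX09166 these were 54 to 66, 2608 to 4878 and 648 to 833 counts. In edgeR, 4640 of 8877 tested genes were called, 2327 higher and 2313 lower. Of these, 1026 were higher and 761 lower by at least 1 on the log2 scale. The 3 deletion and 3 Ku70 libraries did not overlap for 59.2% of genes, where chance gives 10%. The balance of directions depended on the processing. Of the called genes, 49.8% were lower with TMM and 35.7% with total count scaling (3030 higher, 1685 lower). With limma on quantile-scaled log2(FPKM + 1), where the test and the kind of value changed as well, 60.9% were lower (1866 higher, 2904 lower). The median log2 fold change of all genes was 0.01, 0.15 and -0.1 in these fits, and 20, 20 and 19 list members were lower.

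Overexpression of POX07071 also went with lower levels of most list members. Again 20 of 23 fell, 1 rose (POX07963) and 2 were not called (POX06835 and POX08882). The cellobiohydrolase genes POX04786 and POX05587 fell from 8390 ± 1000 to 421 ± 165 FPKM and from 4800 ± 163 to 420 ± 198 FPKM (19.7-fold and 11.3-fold lower, SD, n = 3). The endoglucanase genes POX01166 and POX05571 were 7.53-fold and 13.1-fold lower. The xylanase genes POX00063 and POX06783 fell 84.5-fold and 70.4-fold, to 12.4 ± 4.4 and 14.2 ± 3.65 FPKM, and POX08484 fell 13.5-fold, from 2390 ± 435 to 176 ± 47.6 FPKM.

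The list median in the overexpression comparison was a log2 fold change of -2.91 (7.53-fold lower), and the list passed against all other genes (camera with an estimated correlation of 0.351, p = 0.018). With the letters as blocks the list did not pass (camera with an estimated correlation, p = 0.0614). Adjusted over the list alone, 20 members were lower and 1 higher, and 21.8% of all tested genes were lower. Without library S of the Ku70 overexpression set, 20 members were lower with a median of -3.034. The rise of POX07963 from 20 ± 3.58 to 29.3 ± 4.15 FPKM (log2 fold change 0.56, SE 0.16, edgeR adjusted p = 0.0124) lost its call without library T of the overexpression group (0.45, adjusted p = 0.0515) or library F of its Ku70 group (0.45, adjusted p = 0.0574). POX06835 stood at 172 ± 7.4 against 141 ± 16.9 FPKM and was called higher without library T of the Ku70 deletion set (log2 fold change 0.29, edgeR adjusted p = 0.0305) or of the Ku70 overexpression set (0.41, adjusted p = 0.0345).

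**Figure D2:**
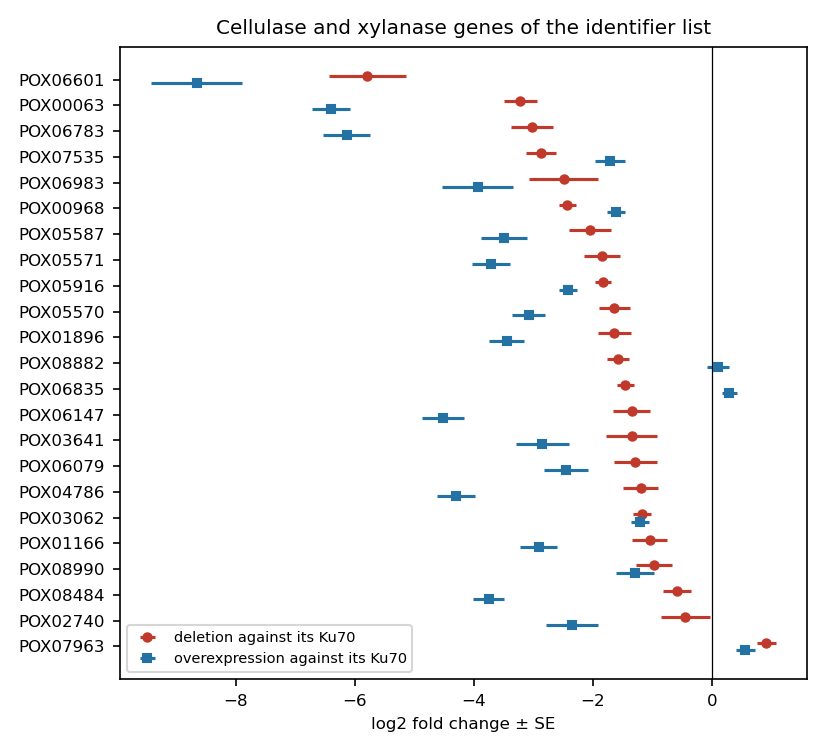
Log2 fold change ± SE (x axis) of the 23 list members (y axis) for deletion against its Ku70 group (red circles) and overexpression against its Ku70 group (blue squares), 3 libraries per group. Called members lie below 0 in both comparisons except POX07963, at 0.91 and 0.56.

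POX09803 and POX03898 had the highest fitted rises in the overexpression strain, a rank that depends on the prior count because both started from 0. They reached 16.4 ± 1.18 and 11.6 ± 3.32 FPKM against 0 counts in the Ku70 group, at least 90.9-fold and at least 89.4-fold higher. Both also rose in the deletion strain, with 3169 to 3519 and 1485 to 2090 counts against at most 1 and 2 per library of its Ku70 group. In the overexpression strain POX03250 rose by 9.35 on the log2 scale (SE 0.29). POX03798 had 133 to 194 counts there against 0 in the Ku70 group. POX09301 and POX08702 had 0 counts in the 3 overexpression libraries against 139 ± 16.1 and 114 ± 30 FPKM in the Ku70 group, at least 359-fold and at least 621-fold lower. edgeR called 3880 of 8877 genes, 1948 higher and 1932 lower, with 944 and 611 of them changed by at least 1 on the log2 scale. Of the called genes 49.8% were lower with TMM and 58.2% with limma on quantile-scaled log2(FPKM + 1) (1727 higher, 2401 lower). Libraries of the 2 groups did not overlap for 56.3% of genes (10% by chance).

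Because deletion and overexpression had separate controls, the responses could be compared without shared libraries. Of 2599 genes called in both comparisons, 2383 changed in the same direction and 216 in opposite directions (Fisher's exact test, odds ratio 122, 95% interval 91.8 to 164). That interval treats genes as independent, which they are not, and does not measure the spread between libraries or strains. Independent lists of these sizes would share 511 genes higher in both and 503 lower in both, and 1207 and 1176 were found. The fold changes correlated across genes at r = 0.733 and Spearman's rho = 0.603, and genes are not independent replicates. On the list, 18 members were lower in both strains.

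The size of the response differed between the strains for 2342 genes (edgeR test of the difference of effects), among them all 216 with opposite directions and 698 with the same direction. Of the 698, the change was larger in the deletion strain for 460 and in the overexpression strain for 238. With total count scaling 31.3% of the genes called for the difference had the lower value in the deletion comparison (1763 higher, 804 lower), against 48.8% with TMM, and the median log2 difference over all genes moved from 0.03 to 0.17. On the list, 12 members fell further in the overexpression strain and 4 in the deletion strain, each against its own Ku70 group. For 7 the difference was not called. Strain and set are not separable here, and differences between the Ku70 groups enter these values. For POX05571 the difference was 1.86, while the Ku70 groups differed by 1.64. Its levels in the deletion and overexpression strains were 206 ± 39.5 and 173 ± 83 FPKM. POX00063 was not called between the Ku70 groups, and its levels in the 2 strains were 165 ± 29.6 and 12.4 ± 4.4 FPKM. The xylanase gene POX00063 changed by 3.18 log2 units more in the overexpression strain (SE 0.37, edgeR adjusted p = 0.000144) and POX08484 by 3.16 (SE 0.34, adjusted p = 6.68e-05). The median difference over the list was 1.46, which did not pass against other genes (camera with an estimated correlation, p = 0.216).

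**Figure D3:**
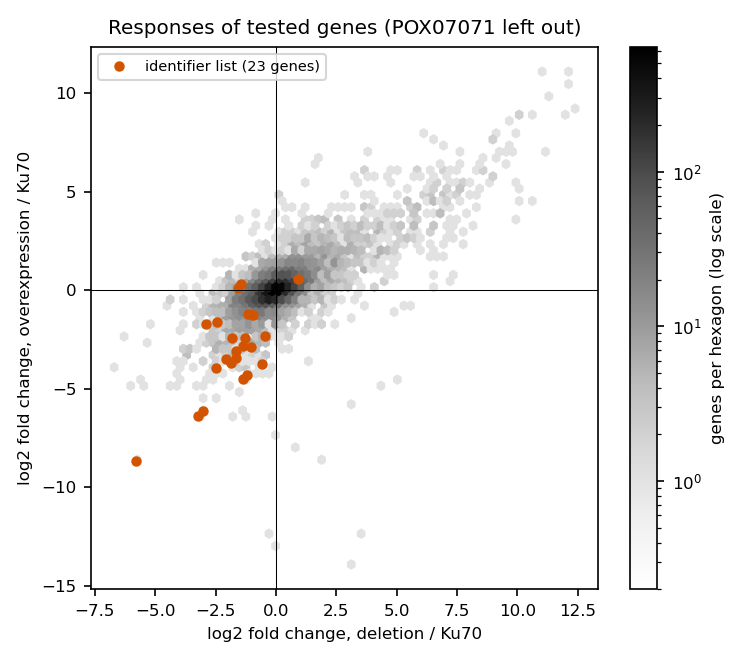
Log2 fold change of tested genes in the deletion comparison (x axis) and the overexpression comparison (y axis), with shading for the number of genes per hexagon (log scale) and the 23 list members in orange. POX07071 is left out, fitted values of genes at 0 counts depend on the prior count, and the correlation across the genes drawn is r = 0.74.

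The longest run of consecutively numbered genes that rose by at least 1 on the log2 scale was chosen after its values were seen and ran from POX05849 to POX05872. All 24 genes rose in the deletion strain, with a median log2 fold change of 5.27 and a median level of 139 FPKM against 3.06 in Ku70. In the overexpression strain 23 of the 24 rose, with a median of 4.34 and a level of 92.5 against 3.04 FPKM. The deletion comparison held 14 runs of 5 or more such genes, whereas at most 2 were found in 1000 shuffles of gene order (permutation p = 0.001, the smallest these can give). The files do not say whether consecutive numbers are neighbours in the genome.

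**Figure D4:**
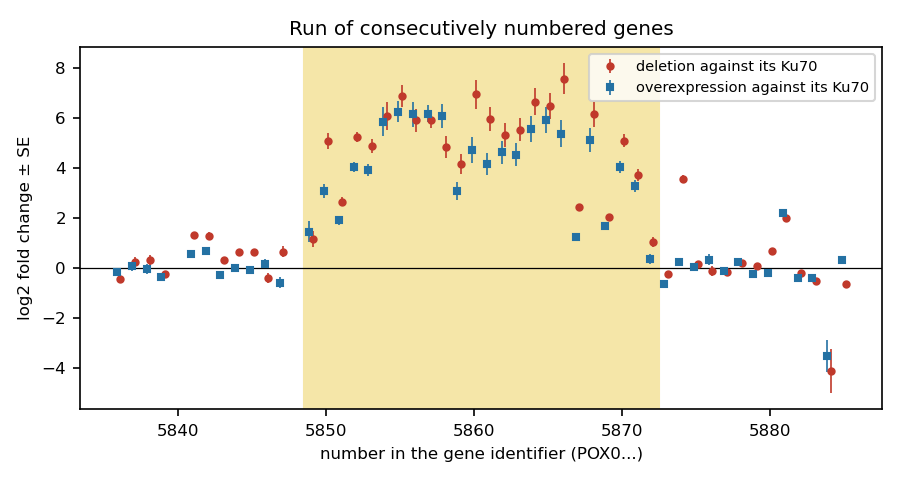
Log2 fold change ± SE (y axis) against the number in the gene identifier (x axis) for deletion (red circles) and overexpression (blue squares), each against its Ku70 group of 3 libraries. Shading marks POX05849 to POX05872, where the medians were 5.27 and 4.34.

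Both Ku70 groups carry Ku70 strain names but different sample titles. Their comparison measures the difference between sets, in which a difference between the strains is not excluded. Cellobiohydrolase genes were higher in the overexpression set: POX04786 by 1.17 log2 units (SE 0.29, edgeR adjusted p = 0.00508) and POX05587 by 0.92 (SE 0.35, adjusted p = 0.0467). The endoglucanase gene POX05571 was higher by 1.64 (SE 0.30, adjusted p = 0.000822). POX00063 and POX06783 were not called (log2 fold changes -0.52 and 0.55). On the list 9 members were higher, 3 lower and 11 not called, the same counts being found for 9 and 3 when adjusted over the list alone, and the list did not pass (camera with an estimated correlation, p = 0.882). POX07071 itself was 1.46-fold higher in the overexpression set (log2 fold change 0.55, SE 0.107, edgeR adjusted p = 0.00207).

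edgeR called 4586 of 8877 genes between the Ku70 groups, 2554 higher and 2032 lower in the overexpression set, of which 542 and 621 differed by at least 1 on the log2 scale. With total count scaling 33.5% of calls were lower (3202 higher, 1614 lower), against 44.3% with TMM, and the median log2 fold change of all genes moved from 0.07 to 0.19. Set and batch of culture or sequencing cannot be told apart, since no library of either set serves in the other.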

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

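The results in this part were picked because the test of the difference between the deletion and overexpression effects passed, and the tests of scaling and of gene length in the first pattern were chosen after the result was seen. The difference passed for 2342 of 8877 genes (edgeR, Benjamini-Hochberg adjusted p under 0.05). Each effect is taken against its own Ku70 group, so unequal Ku70 levels enter the difference. On the log2 scale, a positive difference means a higher value in the deletion comparison. Among cellulase genes of the list it was 3.11 for POX04786, 1.86 for POX01166, 1.81 for POX01896, 1.9 for POX02740, 1.44 for POX05570, 1.86 for POX05571 and 3.16 for POX06147. Without library T of the Ku70 deletion set POX02740 had a deletion effect of 0.1955. Among the xylanase genes it was 3.18 for POX00063, 0.6 for POX05916, 2.87 for POX06601, 3.11 for POX06783 and 3.16 for POX08484.

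POX07535 (-1.17), POX00968 (-0.81), POX06835 (-1.75) and POX08882 (-1.67) fell more in the deletion comparison. POX07535 and POX00968 also differed between the Ku70 groups, by -1.26 and -1.33, while POX06835 and POX08882 were not called there. Of the members above with a positive difference, POX04786 (1.17), POX01166 (1.13), POX01896 (0.83), POX05571 (1.64) and POX06147 (1) were higher in the Ku70 overexpression set. POX05916 was lower in it (-1.44), and the others were not called between the Ku70 groups. POX03250 rose more in the deletion strain, by 3.04, and POX09166 fell more there, by a difference of -3.74. For POX09301 and POX08702, which had 0 counts in the overexpression strain, a fitted fold depends on the prior count. Their differences had edgeR adjusted p of 1.61e-07 and 3.02e-07, with 1111 to 1564 and 8022 to 9603 counts in the deletion libraries.

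Deletion and overexpression of POX07071 moved most shared genes in the same direction, which is the first pattern weighed. Scaling set by a few abundant genes shifts all genes of a comparison one way, but at least 90.9% of the genes called in both comparisons shared a direction under 3 other scalings (50% to 51.8% for independent lists), with 946 or more lower and 1008 or more higher in both. A gene length trend would need both fold changes to follow length, and their Spearman correlations with it across genes were -0.075 and -0.013. Of 100 regroupings of libraries within the sets, 1 gave a correlation as high as the real 0.733, namely the real grouping. Its mirror image counted as the same grouping, and the highest other was 0.608. Exchanging the strain and Ku70 labels in the overexpression set alone only turned the sign (r = -0.733). Regroupings that mix strain and Ku70 libraries weaken the strain effects, and the correlation with them. The count therefore bears on whether there were strain effects, and leaves chance undecided for their shared direction. A response of the fungus to any departure from the normal POX07071 dose may be part of the shared direction. Handling shared by transformed strains may be part of it too, and these groups do not separate the causes.

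For the difference of effects, 2 of the 100 regroupings gave as many calls as the real 2342, the real one included, and 2 of 100 gave as many opposite calls as the real 216. The other was the exchange of strain and Ku70 labels in the overexpression set alone, which turned the shared responses into differences (5262 calls, and 2383 opposite). Regrouping within a set also moves the strain effects into the spread between libraries, so these counts bear on whether there was any strain effect and not on whether the effects were equal. They leave chance undecided for the difference of effects and for opposite calls.

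The 6 libraries of a single comparison allow 10 splits, too few for a share under 0.05. In each case only the real split, 1 of 10, gave as large a result. The deletion comparison had 4640 calls and the highest other split 0, overexpression 3880 and 0, and the Ku70 groups 4586 and 4. The size of the list median was 1.58 against at most 0.789 for deletion and 2.91 against at most 0.907 for overexpression.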

How the results depend on the processing

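Counts of called genes kept within 1.5 times of their values under each alternative except an absolute log2 fold change of at least 1, which left 1787 deletion, 1555 overexpression, 1163 Ku70 and 1096 difference calls and 25 opposite calls, by construction of the stricter limit. With each of the 12 libraries left out in turn, deletion calls ranged from 3950 to 4958, overexpression calls from 3160 to 4398, Ku70 calls from 3844 to 4597, difference calls from 1823 to 2956 and opposite calls from 149 to 314. DESeq2 gave 4684 deletion and 3966 overexpression calls. With the Ku70 libraries of the other set as control, 5672 and 5610 genes were called.

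For the list in the deletion comparison (median log2 fold change -1.578, camera with an estimated correlation p = 0.111), leaving out libraries gave medians of -1.691 to -1.355 (camera p = 0.0786 to 0.135). It passed with camera at a preset correlation (-1.578, p = 6.85e-07), with fry (-1.578, p = 5.95e-05), which does not compare the list with other genes, and with limma at pseudocounts of 1 (-1.295, p = 0.0439), 0.1 (-1.408, p = 0.0453) and 5 (-1.236, p = 0.0416) and without a trend (-1.295, p = 0.0439). The cause was not tested. In the overexpression comparison the medians without single libraries were -3.242 to -2.751 (camera with an estimated correlation, p = 0.0129 to 0.0252), and 20 members were lower in each.

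The letters F, S and T were checked for pairing by the correlation of deviations between libraries with the same letter. It was 0.06, -0.01 and 0.1 in the deletion set and 0.02, 0.14 and 0.23 in the overexpression set. Libraries F and T of the deletion group and S and T of the overexpression group correlated best with their own letter. Library S of the deletion group and F of the overexpression group did not. With 3 libraries per group these values cannot exclude pairing, which stays open. The replicate block gave 4571 deletion, 3863 overexpression, 4552 Ku70, 2242 difference and 223 opposite calls. The list median was -1.566 (camera with an estimated correlation, p = 0.168) for deletion and -2.97 (p = 0.0614) for overexpression, which no longer passed, with 4 residual degrees of freedom in place of 8.

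For single named genes 1320 of 1350 values kept direction and call, 16 lost and 13 gained a call, and 1 turned: POX02740 in the deletion comparison, from -0.7163 without library S of the Ku70 deletion set to 0.1955 without T. POX03641 lost its deletion call in 8 settings, among them limma at a pseudocount of 1 (adjusted p = 0.058) and edgeR with the block (adjusted p = 0.0581), and POX01166 in limma with quantile scaling (-0.5493, adjusted p = 0.102). The POX07071 rise ranged from 4.236 to 4.443. At 13882665 to 15300876 expected counts, 22% of simulated 1.5-fold changes were recovered for deletion, in simulations where few genes changed. With 4640 deletion calls in the data the adjusted p limit is less strict, so this share need not hold there. How many small changes were missed in the data was not measured.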

Other observations

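The tests of a batch between the sets and of a missing stretch of DNA, and the genes named in this part, were chosen after the results were seen. POX01764 took 3.23 ± 0.34% of all counts in the deletion strain against 0.12 ± 0.051% in its Ku70 group (SD, n = 3), and 1.54 ± 0.11% in the overexpression strain against 0.191 ± 0.06%. POX06051 took 3.24 ± 0.23% in the Ku70 overexpression set against 0.752 ± 0.31% in the Ku70 deletion set and 0.939 ± 0.15% in the overexpression strain. POX07072, numbered next to POX07071, was lower in the deletion strain (log2 fold change -1.84, SE 0.16, edgeR adjusted p = 1.4e-06) and not called in the overexpression strain (-0.29, adjusted p = 0.144), and the difference passed (-1.55, SE 0.22, adjusted p = 0.000396). Of the other 9 genes within 5 numbers of POX07071, POX07070 (0.55, edgeR adjusted p = 0.00288) and POX07073 (1.78, adjusted p = 0.00255) were higher in the deletion strain, and POX07066 (-0.22, adjusted p = 0.0359) and POX07067 (-0.44, adjusted p = 0.0219) were lower. For these 4 the difference of effects did not pass (edgeR adjusted p of 0.239, 0.0566, 0.0849 and 0.533). Runs of at least 5 consecutively numbered genes changed by at least 1 on the log2 scale were also found among falls, with 7 in the deletion and 6 in the overexpression comparison, and among the Ku70 groups, with 3 higher and 2 lower. In 1000 shuffles of gene order at most 1 was found in each of these cases. The longest falling run in the deletion strain spanned POX09326 to POX09340 (12 tested genes, median -2.06), and in the overexpression strain POX09332 to POX09340 (9 genes, median -2.77).

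The Ku70 groups differed for 4586 genes, the second pattern weighed. Reads shared between genes were argued against by the genes with whole counts in all 12 libraries, of which 51.5% were called, against 53.1% of the others. A gene length trend was present (Spearman's rho 0.22 across genes), but its removal left 4368 calls. A culture or sequencing batch may remain: the lowest share of genes with counts that are not whole in the overexpression set was 3 times the highest in the deletion set (2.56% against 0.854%), and set and batch cannot be told apart here. No biological explanation was tested. Both groups carry Ku70 strain names, which does not exclude a difference between the strains.

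The third pattern is a group of 4 genes with at most 2 counts in total in the 3 overexpression libraries and at least 100 counts in each of the other 9: POX05007, with 2 counts, and POX08702, POX08703 and POX09301, with 0 counts and at least 621-fold, 193-fold and 359-fold lower than in the Ku70 libraries of the set. POX07071 was the only such gene in the deletion libraries, and the Ku70 groups had 0. Down-regulation as the tail of the response may be enough at POX09301. The xylanase gene POX06601, which was still detected, had 0.00242 of its Ku70 level. This was 0.868 times the largest ratio that the floor allows for POX09301 (0.00279). The Ku70 level of POX06601 varied widely (278 ± 262 FPKM, SD, n = 3), so its ratio is unsteady. POX05007 and POX08702 fell at least 1490-fold and 621-fold, further than the fitted 403-fold of POX06601, which therefore gives no measure for them. A stretch of DNA missing from the strain may be the cause at POX09301, the only place tested for it: the 3 genes numbered after it had 0 counts where 22.2 were expected (exact binomial p = 2.59e-07, which covers counting error only and not the spread between libraries). Both stay open there, a missing stretch was not tested at POX05007, POX08702 and POX08703, and DNA of the strain was not analysed here.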
